A study of Rattus norvegicus with 4 samples.

How the data were processed

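The series holds 4 RNA-seq libraries from neonatal rat ventricular myocytes, 2 infected with a control hairpin and 2 with a Crat hairpin. The labels call the arms wild type and knockout, and the design text describes hairpins; they are named control and Crat hairpin here. Total RNA was sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name kallisto and DESeq2, without versions, and the rat build mRatBN7.2. How gene values were summed, rounded or filtered is not given in the sources used here.

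The authors deposited a single table of 14318 rows with a gene identifier, a symbol, a value per library, a mean per group, a p-value and an adjusted p-value. The library columns are headed TPM, per the file headers, but every value is a whole multiple of a step that is constant within a library, so the deposited signal is RPM (reads scaled to the library total) with no division by gene length. In each library 100% of the values came out whole within 0.02 of a read. Dividing by the step gave back the reads, 23680064, 1321735, 321516 and 1622998 in all. No gene has fewer than 10 reads summed over the libraries. The 14318 rows describe 14137 gene identifiers, because 140 identifiers stand on several rows with different symbols and the same values. Such an identifier was used once. The deposited adjusted p-value equals a Benjamini-Hochberg adjustment over all 14318 rows, to within 7.5e-09. The 1551 identifiers without a symbol were tested and counted, but not named beyond 4 examples. The RefSeq gene table at hand is of another assembly, GRCr8, and matched 0 identifiers, so names come from the deposited table and no coordinates are given.

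Before the data were examined, the groups, the test, 36 gene lists, the naming rule and most alternatives were fixed. Design and test assumed TPM; the same test was kept for RPM. Genes with a mean of at least 1 RPM over the 4 libraries were kept. Values were taken as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, with a variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and can understate the change of low genes. Where a library of a group has few or no reads they can also exceed other estimates. Nop16 had -3.14 here and -1.95 in edgeR, and Mx2 had 7.32 and 5.67. Lists of at least 5 tested members, without Crat, were compared with all other genes by camera with a preset correlation of 0.01, two-sided, adjusted over the 36 lists. With the correlation estimated from the residuals, 0 of the 19 lists past the threshold passed. That version takes its degrees of freedom from the few libraries and not from the number of genes. It is therefore strict for every list here, whatever the correlation.

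The text names Crat; the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 and no overlap between groups, a condition that chance meets in 33.3% of genes; and members of each list, up to 4 past the threshold by size of change, or up to 2 by mean where fewer than 2 passed. A few further members are named as exceptions, counts or values and were chosen after their values were seen, among them Ifitm1, Mybpc3, COX1, COX2, COX3, ND1, ND2, Rplp0 and Cd68. Where no read was found in a group, a floor of 3 reads over the group was used, which covers counting error only.

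Nothing in the labels says that the libraries of a group came from separate cultures, so the spread behind the p-values may be technical. For each gene that spread is partly taken from other genes of similar mean through the variance trend. Without the trend 345 genes changed, against 2454 with it. The fit also gives all 4 libraries the same variance, although their depth differs 73.7-fold. An exact permutation test of 2 against 2 cannot go below p = 0.333. A chi-square test of the reads over genes gave 1.47 per degree of freedom for the control pair over 11092 genes (p = 4.3e-210) and 1.29 for the Crat hairpin pair over 8481 genes (p = 6.8e-67), so neither pair is a library deposited again within counting error. The test covers counting error only: the excess may come from amplification or library preparation, and it does not show separate cultures. The libraries were counted as 2 per group because the labels list them as separate samples.

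The fit was tested on simulated reads for this comparison, with the real means and library sizes and 200 changed genes among 12709 tested. Dispersions came from the trend over the mean, so genes of equal mean shared a value. It recovered 9 of 67 genes changed 1.5-fold, 32 of 67 changed 2-fold and 51 of 66 changed 4-fold, and called 0 of 12509 unchanged genes. The real data had far more changed genes and spread beyond the trend, so the count of false calls holds for the simulated setting only. Alternatives were other pseudocounts, filters, scalings, variance priors, a replicate block, each library left out, mitochondrially encoded genes left out, a threshold of 0.1, the authors' calls, and other list tests. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, which called 3840 and 1616 genes. So was thinning to the shallowest library, done as a single random draw. No column of per-sample values was left unused.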

Results

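Expression was measured by RNA sequencing in neonatal rat ventricular myocytes, a primary culture of heart muscle cells that also carries other cells of the heart. Cultures were infected with lentivirus carrying a control short hairpin RNA or a hairpin against Crat, and RNA was taken at day 5. Crat encodes carnitine acetyltransferase, the mitochondrial enzyme that moves acetyl groups between coenzyme A and carnitine. There were 4 libraries, 2 per group, and the only comparison was Crat hairpin against control hairpin. It asks how the transcriptome of these cells differs once Crat is depleted, in a study whose title concerns dilated cardiomyopathy. Depth was very uneven. The reads behind the values came to 23680064 and 1321735 in control replicates 1 and 2, and to 321516 and 1622998 in Crat hairpin replicates 1 and 2, a 73.7-fold spread. A single read was therefore worth 0.0422 and 0.757 RPM (reads scaled to the library total) in the control libraries and 3.11 and 0.616 in the Crat hairpin libraries, and the knockdown values of weakly expressed genes rest on few reads.

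Crat itself fell by 2.72 ± 0.19 on the log2 scale (SE, 2 libraries against 2; limma, Benjamini-Hochberg adjusted p = 7.3e-06). It stood at 148 and 156 RPM in the control libraries and at 24.9 and 19.7 in the Crat hairpin libraries, where it was counted with 8 and 32 reads. With the reads of every library thinned to the total of the shallowest in a single random draw, the fall was 2.65 with a limma adjusted p = 0.0973. The call on Crat was thus lost at that depth in this draw, and other draws were not made.

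Among named genes the largest changes were mostly rises of interferon-stimulated genes. Rsad2, which encodes the antiviral enzyme viperin, rose from 3.29 and 1.51 to 1061 and 1128 RPM, a log2 fold change of 8.38 ± 0.25 (SE). Ifit3, an antiviral protein that restricts viral RNA, rose by 7.99 ± 0.15, Oasl by 8.05 ± 0.29 and Cmpk2 by 7.58 ± 0.36. Control replicate 2 held only 2 reads of Rsad2, 6 of Ifit3, 2 of Oasl and 1 of Cmpk2. Their SE is partly taken from other genes of similar mean and can fall below the counting error of so few reads. The chemokine Cxcl10, which draws T cells, rose by 8.05 ± 0.57, although control replicate 2 held no read of it and the Cxcl10 log2 fold change ran from 6.91 to 9.19 with a control library left out, and the antiviral GTPases Mx2 and Mx1 rose by 7.32 ± 0.76 and 7.06 ± 0.42. Mx2 differed between the controls, 15.6 and 0.757 RPM, and the Mx2 log2 fold change was 8.94 without control replicate 1 and 5.70 without control replicate 2, while the Mx1 log2 fold change was 7.87 and 6.24. Mx2 lost the call under the robust prior (adjusted p = 0.0937) and without a variance trend (adjusted p = 0.0760). Complement C2, the chemokine Ccl5 and the GTPase Gbp5 completed the 10 largest rises among named genes, at log2 fold changes of 7.05, 6.82 and 6.60. All 10 had adjusted p at or below 1.4e-04. After thinning to the shallowest library Cxcl10, Oasl, Ifit3, Mx1 and Mx2 no longer passed (adjusted p = 0.0641, 0.0619, 0.0719, 0.0851 and 0.112), while the values stayed as large: the Cxcl10 log2 fold change was 8.26, the Oasl log2 fold change 8.83, the Ifit3 log2 fold change 9.05, that of Mx1 7.74 and that of Mx2 7.90. Among 5 genes passed over because they carry no name in the table, ENSRNOG00000068984 rose by 9.07 and ENSRNOG00000056947 by 8.18.

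**Figure D1:**
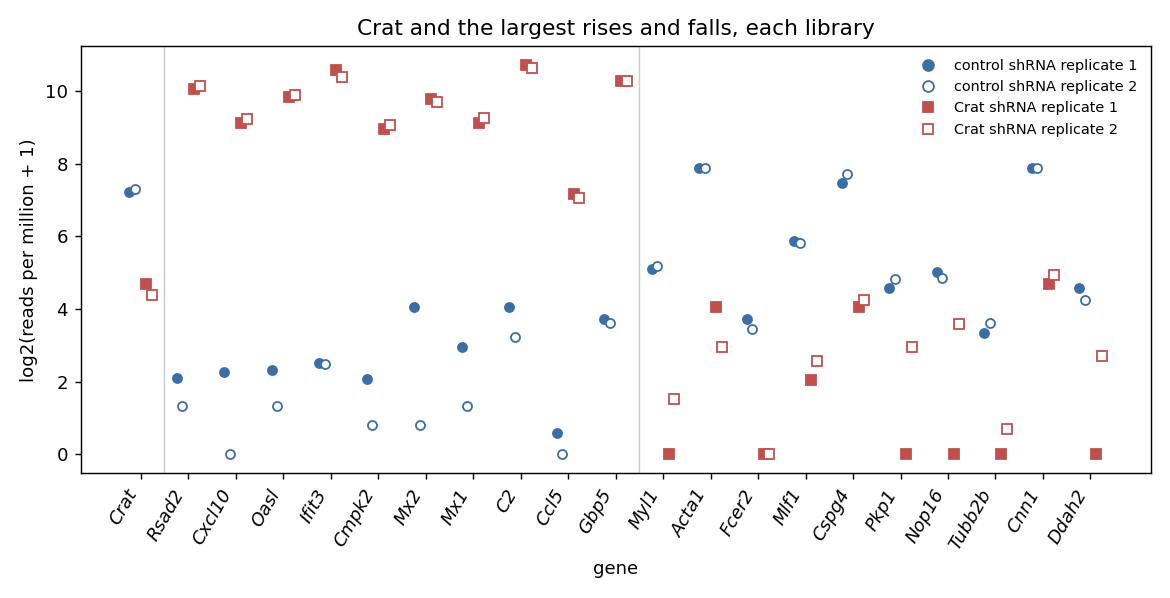
Level of Crat, of the 10 largest rises and of the 10 largest falls in each library, as log2 of RPM plus 1; circles are the 2 control hairpin libraries, squares the 2 Crat hairpin libraries, and filled symbols replicate 1. Rsad2 lies at 1061 and 1128 RPM in the Crat hairpin libraries against 3.29 and 1.51 in the controls, and Fcer2 has no read in either Crat hairpin library.

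Of 44 tested interferon-stimulated genes, 43 rose and 0 fell, and adjusted over the list alone 43 rose as well; Ifitm1 did not pass, with a log2 fold change of 0.18. The list stood above the other genes (camera adjusted p = 3.1e-47; adjusted p = 0.239 with an estimated correlation). The antigen presentation list behaved alike, with 16 of 17 members higher, and 16 adjusted over the list alone (adjusted p = 5.0e-19; adjusted p = 0.239 with an estimated correlation). The class I chain RT1-S3 rose by 5.16, the immunoproteasome subunit Psmb8 by 4.78, the class I chain RT1-A1 by 4.41 and Nlrc5, the activator of class I transcription, by 3.78. Class I chains are a family of close copies whose reads can be shared, so their separate values are uncertain. Among cytokines and chemokines 23 of 28 rose and none fell, 25 adjusted over the list alone (adjusted p = 1.3e-18; adjusted p = 0.194 with an estimated correlation), including Cxcl11 at 6.20, Cx3cl1 at 3.34 and Cxcl3 at 3.02.

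The list of cytosolic nucleic acid sensing holds sensors, nucleases, endosomal receptors and signalling genes. Its members rose in 9 cases of 23 and fell in 1, and adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 0.00172, and 0.239 with an estimated correlation). Aim2, a sensor of cytosolic DNA, rose by 4.80, the DNA exonuclease Trex1 by 2.37, the endosomal RNA receptor Tlr3 by 1.82 and the kinase Ikbke by 1.70. Of 14 inflammasome and pyroptosis genes 5 rose and none fell, 6 adjusted over the list alone (adjusted p = 0.0134; adjusted p = 0.240 with an estimated correlation). They included Ninj1, which ruptures the membrane of dying cells, at 1.14, and the inflammatory caspase Casp4 at 1.07. Without control replicate 2 this list did not pass (adjusted p = 0.127).

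None of the 12 leukocyte markers tested passed the limma test, adjusted over all genes or adjusted over the list alone, and the list did not pass (camera adjusted p = 0.961); its median and mean log2 fold changes were 0.25 and 0.24 while the camera direction was down. By fry, which compares with no change, it passed upward (adjusted p = 0.0245). Cd68 stood at 6.11 and 11.1 RPM in the control and Crat hairpin groups, Fcer1g at 9.65 and 8.69, and Laptm5 at 8.34 and 9.92.

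Cholesterol synthesis genes fell. Of 26 tested, 17 fell and 0 rose, and adjusted over the list alone 20 fell and 1 rose (camera adjusted p = 4.3e-15; adjusted p = 0.194 with an estimated correlation). Hmgcs1, which makes HMG-CoA, fell from 578 and 561 to 236 and 231 RPM, a log2 fold change of -1.28 ± 0.08. The mevalonate kinase Mvk fell by 1.65 and the sterol reductase Tm7sf2 by 1.49. Of 14 bile acid and oxysterol synthesis genes 4 rose and none fell, 4 adjusted over the list alone (adjusted p = 0.0378; adjusted p = 0.264 with an estimated correlation). These were the sterol 27-hydroxylase Cyp27a1 at 3.43 ± 0.17, the oxysterol 7-alpha-hydroxylase Cyp7b1 at 2.64, Hsd3b7 at 2.07 and the sterol carrier Scp2 at 0.75. Without Crat hairpin replicate 1 this list no longer passed (adjusted p = 0.140). Among cholesterol efflux and LXR target genes 5 of 17 rose and 1 fell (2 and 1 under median-of-ratios scaling), and 6 and 1 adjusted over the list alone (adjusted p = 0.154). Nr1h2, which encodes LXR beta, rose by 2.07 and the desaturase Scd fell by 1.47.

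Fuel genes moved in both directions. In the carnitine shuttle list 6 of 16 rose and 2 fell (3 and 2 under median-of-ratios scaling), and 8 and 2 adjusted over the list alone (camera adjusted p = 0.164). Cpt2 and Cpt1a, the inner and outer carnitine palmitoyltransferases of mitochondria, rose by 2.07 ± 0.23 and 1.72 ± 0.22. In mitochondrial fatty acid oxidation 5 of 25 rose and 2 fell (4 and 4 under median-of-ratios scaling), also adjusted over the list alone (adjusted p = 0.866). The lipase inhibitor Angptl4 rose by 4.23 and the fatty acid binding protein Fabp3 by 2.05, while the medium-chain dehydrogenase Acadm fell by 1.56. In the peroxisome list 1 of 30 rose and 1 fell, and 1 and 0 adjusted over the list alone (adjusted p = 0.992); Cat, the catalase that removes hydrogen peroxide, rose by 2.54 and Phyh fell by 0.57. Of 24 glycolysis genes 4 rose and 8 fell (3 and 12 under median-of-ratios scaling), the same counts adjusted over the list alone (adjusted p = 0.00573; adjusted p = 0.239 with an estimated correlation). The lactate carrier Slc16a3 fell by 2.08 and the insulin-dependent glucose carrier Slc2a4 by 1.31. The glycolysis list did not pass by fry (adjusted p = 0.0952).

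Transcripts of the mitochondrial genome fell in every case. All 13 fell, and all 13 adjusted over the list alone (camera adjusted p = 3.3e-32; adjusted p = 0.194 with an estimated correlation). ND4L, a subunit of respiratory complex I, fell by 2.45 ± 0.08, CYTB of complex III by 2.29 ± 0.04, and ND4 and ND5 of complex I by 2.13 ± 0.06 and 2.12 ± 0.05. Sizes did not follow the complexes: ND1 and ND2 of complex I fell by 1.22 and 1.25, and COX1, COX2 and COX3 of complex IV by 0.89, 1.54 and 1.53. The 13 genes made up 9.47% and 9.08% of the reads in the control libraries and 3.64% and 3.62% in the Crat hairpin libraries. Nuclear genes of the respiratory chain fell in 26 of 60 cases and rose in 0, and adjusted over the list alone 32 fell (adjusted p = 3.1e-13; adjusted p = 0.194 with an estimated correlation), by 1.41 for Cox6c, 1.28 for Ndufa4, 1.21 for Uqcrh and 1.19 for Atp5mf. In the tricarboxylic acid cycle 9 of 28 fell and 1 rose (16 and 1 under median-of-ratios scaling), and 13 and 3 adjusted over the list alone (adjusted p = 3.0e-05; adjusted p = 0.194 with an estimated correlation). The ligase subunit Sucla2 fell by 1.07 and citrate synthase, Cs, by 0.69, while the kinase Pdk2, which inhibits pyruvate dehydrogenase, rose by 1.06. In the list of mitochondrial dynamics, import and DNA maintenance 3 of 30 rose and none fell, 2 adjusted over the list alone (adjusted p = 0.992), with Gabpa at 1.74, while under median-of-ratios scaling 2 rose and 5 fell; its median of 0.13 and mean of 0.17 were positive and the camera direction was down.

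**Figure D2:**
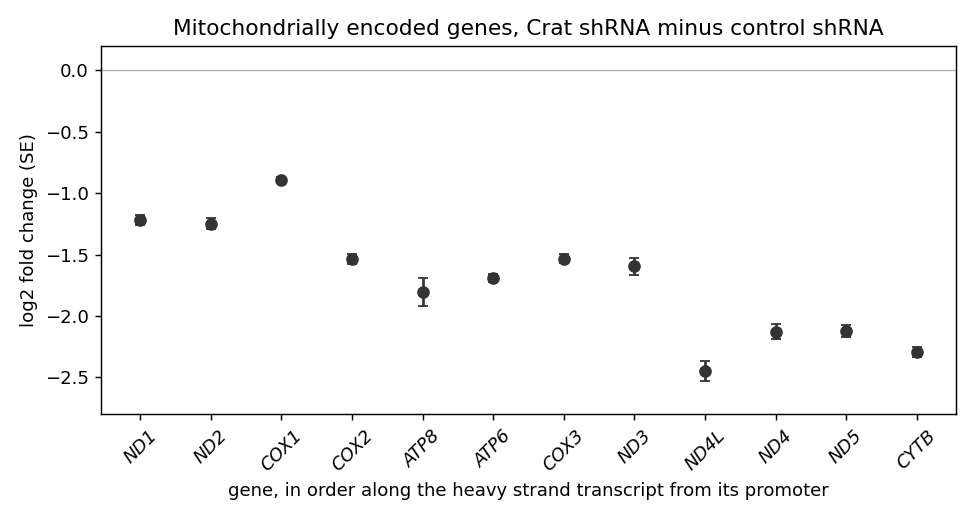
Log2 fold change of 12 mitochondrially encoded genes, Crat hairpin minus control hairpin, in their order along the heavy strand from its promoter; points are limma estimates from 2 libraries per group and bars are SE. ND1 fell by 1.22 at the start of the order and CYTB by 2.29 at its end.

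Sarcomere genes fell. Of 33 tested, 25 fell and 1 rose, and 26 and 2 adjusted over the list alone (camera adjusted p = 2.9e-23; adjusted p = 0.194 with an estimated correlation). The cardiac actin Actc1 fell from 7721 and 7728 to 1888 and 1752 RPM, a log2 fold change of -2.09 ± 0.04. The skeletal actin Acta1 fell by 4.39 ± 0.31, the troponin subunit Tnnc1 by 2.21 and Smyd1, a methyltransferase of muscle, by 2.01. The member that rose was Mybpc3, myosin binding protein C, at 0.41. Genes of dilated cardiomyopathy went both ways, 13 of 31 down and 8 up, and 13 and 9 adjusted over the list alone (adjusted p = 0.00488; adjusted p = 0.240 with an estimated correlation); Sgcd fell by 2.50 and Des, desmin, by 1.30, while Sgcb rose by 1.41. That list did not pass by fry (adjusted p = 0.0952) or by ranks (adjusted p = 0.0781). Calcium handling and ion channel genes fell in 7 of 30 cases and rose in 4, and 8 and 5 adjusted over the list alone (adjusted p = 0.123), with a median of 0.08 and a mean of -0.12. Casq2, the calcium store protein, fell by 1.10 and the channel Cacna1g rose by 0.98. Of 20 stretch and hypertrophy genes 9 fell and 4 rose (9 and 2 under median-of-ratios scaling), and 9 and 6 adjusted over the list alone (adjusted p = 0.00323; adjusted p = 0.240 with an estimated correlation). Cnn1 fell by 3.08, Ccn2 by 2.08 and Fhl1 by 2.04, while the cytokine Gdf15 rose by 1.51. The list lost its call under quantile normalization (adjusted p = 0.145) and by ranks (adjusted p = 0.171).

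The 10 largest falls among named genes also held Myl1 at -4.39, with no read in Crat hairpin replicate 1, Mlf1 at -3.54 and Cspg4, a pericyte proteoglycan, at -3.46. Fcer2 had 12.2 and 9.84 RPM in the controls and none in the Crat hairpin libraries, and was at least 7.13-fold lower when the knockdown group is set to a floor of 3 reads over the group. Pkp1, Nop16, Tubb2b and Ddah2 fell by 3.22, 3.14, 3.14 and 3.07, each with no read in Crat hairpin replicate 1. The Nop16 log2 fold change was -1.34 without that library and -4.94 without Crat hairpin replicate 2, the Pkp1 log2 fold change was -1.74 and -4.70, and the Ddah2 log2 fold change was -1.71 and -4.43. Myl1 lost its call without control replicate 1 (adjusted p = 0.103), and the Myl1 log2 fold change ran from -3.64 to -5.15 with a Crat hairpin library left out. The Fcer2 log2 fold change lost its call without either control library (adjusted p = 0.283 and 0.312), and so did Pkp1 (adjusted p = 0.303 and 0.0676), Ddah2 (adjusted p = 0.375 and 0.0615) and the Tubb2b log2 fold change (adjusted p = 0.271 and 0.464); Nop16 lost it without control replicate 1 (adjusted p = 0.409). After thinning to the shallowest library Cspg4 and Cnn1 passed among the 10, and the log2 fold changes of Myl1, Acta1, Fcer2, Mlf1, Pkp1, Nop16, Tubb2b and Ddah2 did not (adjusted p = 0.118, 0.0719, 0.0955, 0.0759, 0.398, 0.344, 0.555 and 0.459). Nop16 also lost its call under the robust prior (adjusted p = 0.0772), in DESeq2 (adjusted p = 0.274) and in the authors' deposited values (adjusted p = 0.340). The unnamed ENSRNOG00000065528 fell by 2.35 and ENSRNOG00000064527 by 2.17.

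**Figure D3:**
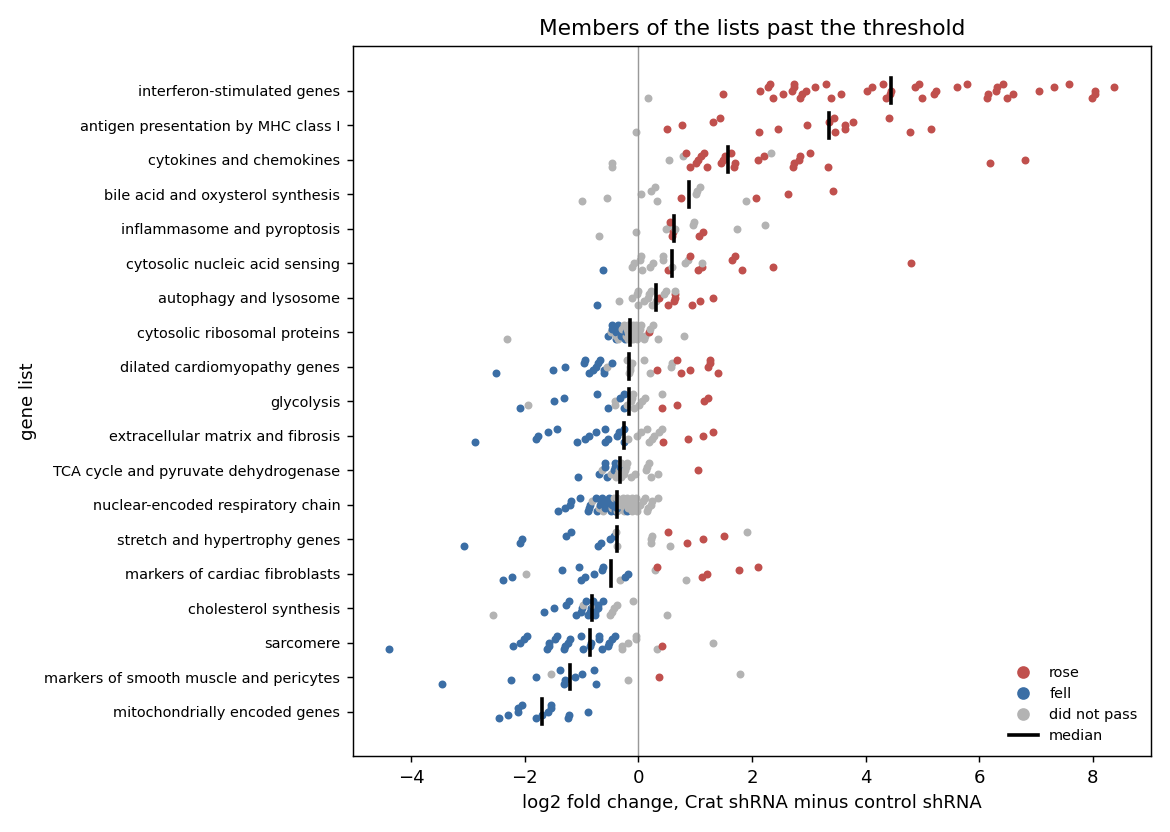
Log2 fold change of each tested member of the 19 gene lists past the threshold, Crat hairpin minus control hairpin; red points rose, blue points fell, grey points did not pass, and black bars are medians. The interferon-stimulated genes have a median of 4.44 and the mitochondrially encoded genes a median of -1.69.

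Of 29 extracellular matrix genes 16 fell and 4 rose, and 17 and 6 adjusted over the list alone (camera adjusted p = 9.9e-06; adjusted p = 0.240 with an estimated correlation). Tgfbi fell by 2.87, Thbs1, thrombospondin, by 1.80 and the growth factor Tgfb3 by 1.59. Smooth muscle and pericyte markers fell in 10 of 14 cases and rose in 1, and 10 and 2 adjusted over the list alone (adjusted p = 3.3e-09; adjusted p = 0.194 with an estimated correlation), among them the smooth muscle actin Acta2 by 2.24 and Myh11 by 1.38. Fibroblast markers fell in 11 of 20 cases and rose in 5, and 12 and 5 adjusted over the list alone (adjusted p = 0.00112; adjusted p = 0.240 with an estimated correlation). The surface glycoprotein Thy1 fell by 2.39 and Islr by 2.23, while the receptor Pdgfra rose by 2.10 and Fbln1 by 1.78. Under quantile normalization neither the matrix list (adjusted p = 0.133) nor the fibroblast list (adjusted p = 0.693) passed. Endothelial markers fell in 2 of 12 cases and rose in 1, also adjusted over the list alone (adjusted p = 0.382; median 0.04, camera direction down); Flt1 fell by 1.44 and Kdr rose by 1.31. In the list of epicardial, Schwann and red cell markers 1 of 8 rose, also adjusted over the list alone (adjusted p = 0.780); this was Upk1b at 1.40, and Ncam1 had a value of 0.06.

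Autophagy and lysosome genes rose in 8 of 23 cases and fell in 1 (5 and 2 under median-of-ratios scaling), and 9 and 1 adjusted over the list alone (camera adjusted p = 0.0308; adjusted p = 0.448 with an estimated correlation), with the lysosomal membrane protein Lamp1 at 1.32 and the autophagy receptor Sqstm1 at 0.95. Under median-of-ratios scaling this list did not pass (adjusted p = 0.259). Ribosomal protein genes fell in 11 of 52 cases and rose in 1 (30 and 0 under median-of-ratios scaling), and 13 and 2 adjusted over the list alone (adjusted p = 1.5e-06; adjusted p = 0.239 with an estimated correlation); Rps28 fell by 0.53, and Rplp0, which rose by 0.18, stood at -0.01 under median-of-ratios scaling. NRF2 and antioxidant genes rose in 5 of 26 cases and fell in 1, and 5 and 2 adjusted over the list alone (adjusted p = 0.443), with the mitochondrial superoxide dismutase Sod2 at 2.21 and the haem oxygenase Hmox1 at 1.34. In the p53 and apoptosis list 9 of 23 rose and 2 fell (4 and 3 under median-of-ratios scaling), and 11 and 3 adjusted over the list alone (adjusted p = 0.202), with the growth arrest gene Gadd45a at 1.40. Integrated stress response genes rose in 7 of 29 cases and fell in 1 (5 and 3 under median-of-ratios scaling), and 9 and 2 adjusted over the list alone (adjusted p = 0.400), with Atf3 at 2.18 and Ddit3 at 1.89.

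Hypoxia targets rose in 4 of 12 cases (3 rose and 2 fell under median-of-ratios scaling), also adjusted over the list alone (camera adjusted p = 0.0739), with the vascular growth factor Vegfa at 1.26. Heat shock genes rose in 4 of 17 cases and fell in 3 (3 and 4 under median-of-ratios scaling), and 6 and 3 adjusted over the list alone (adjusted p = 0.992); Hspb8 rose by 1.38 and Hspb1 fell by 1.28. Chaperones of the endoplasmic reticulum rose in 3 of 21 cases and fell in 2 (1 and 3 under median-of-ratios scaling), also adjusted over the list alone (adjusted p = 0.481; median 0.02, camera direction down), and Hspa5 fell by 0.59. Immediate early genes rose in 2 of 13 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.701; median 0.06, camera direction down), with Ier3 at 0.94. In the cell cycle list 1 of 34 rose and 1 fell, and 0 and 1 adjusted over the list alone (adjusted p = 0.435; median 0.02 and mean -0.06); the cyclin Ccnd1 fell by 1.35 and Tyms rose by 0.67.

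In all, 2454 of 12949 tested genes changed, 1631 higher and 823 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Median-of-ratios scaling gave 1044 higher and 1254 lower, and quantile normalization 953 higher and 1118 lower: the median log2 fold change of all genes was 0.15 on the values as deposited and -0.03 under either scaling, so small rises are relative to that shift. The count also moved with a library left out, where the library left alone in its group is assumed to vary like the other pair. It was 601 without control replicate 1, 1271 without control replicate 2, 3882 without Crat hairpin replicate 1 and 6252 without Crat hairpin replicate 2, and 169 genes passed after thinning to the shallowest depth. In the authors' deposited table an adjusted p under 0.05 was reached by 1486 genes. That table gives no fold change, so their direction was taken here from the group means of the deposited values, 694 higher and 792 lower. Of these, 684 were higher and 692 lower in the limma fit too. That 0 went the opposite way was nearly fixed beforehand, since both directions come from the same 4 libraries and values.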

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

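Calls depended on depth, and Crat hairpin replicate 1 had 321516 reads. Thinned to that depth in a single draw, 169 genes changed (110 higher, 59 lower), 168 of them shared with the authors' deposited calls. Crat had -2.65 without passing, and 115 of 149 other named genes kept their direction but not their call. Fewer reads must lower the number of calls, so thinning does not show what limits them at the full depth. Thinning, edgeR and DESeq2 were chosen after seeing the data. Without a variance trend 345 genes changed (266 higher, 79 lower; 319 shared with the authors' deposited calls), and 94 named genes lost the call. edgeR gave 3840 genes, 2065 of them lower, and DESeq2 1616, 749 of them higher. The authors' deposited adjusted p gave 1486, 694 of them higher by the deposited group means. Median-of-ratios scaling gave 1044 higher and 1254 lower, and quantile normalization 953 higher. With a library left out, its partner being assumed to vary like the other group, the count ran from 601 to 6252 (higher 425 to 3632, lower 176 to 2620), and the agreement with the authors' p values from 599 to 1436 shared calls. Pseudocounts, filters, the robust prior and the threshold of 0.1 kept the counts within 1.5 times. Except where stated, the cause was not tested.

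Deviations of same-numbered libraries correlated at 0.00612, and at 0.0235 over genes with a mean above 50 RPM. Much of these deviations is counting error, so a real pairing could go unseen and is not excluded. A replicate block gave 2596 genes, 1701 higher and 895 lower, and turned only the direction of the mitochondrial dynamics list (adjusted p = 0.970).

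With an estimated correlation 0 lists passed. The adjusted p was 0.239 for interferon-stimulated genes, nucleic acid sensing, antigen presentation, glycolysis and ribosomal proteins. It was 0.240 for the inflammasome, dilated cardiomyopathy, stretch, matrix and fibroblast lists, and 0.194 for cytokines, cholesterol synthesis, the tricarboxylic acid cycle, the respiratory chain, mitochondrially encoded genes, sarcomere and smooth muscle. It was 0.264 for bile acid synthesis and 0.448 for autophagy. Correlation between genes does not account for all of this. The estimates were -0.019 for sarcomere and -0.021 for cholesterol synthesis, below the preset 0.01. Their unadjusted camera p still rose from 2.4e-24 to 0.0072 and from 7.2e-16 to 0.012. This version takes its degrees of freedom from the few libraries. For interferon-stimulated genes the estimate was 0.55, for mitochondrially encoded genes 0.33 and for antigen presentation 0.32. It was 0.12 for autophagy and 0.10 for cytokines. All of these lie above the preset, so correlation can have raised their p as well, and the 2 effects were not separated.

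By fry, lists that newly passed in the same direction were LXR targets (adjusted p = 0.0166), carnitine shuttle, p53 and hypoxia (0.0245 each) and NRF2 (0.00628). Lists that lost the call were glycolysis and dilated cardiomyopathy (0.0952 each) and fibroblasts (0.0670). The direction turned for leukocytes (0.0245) and mitochondrial dynamics (0.0412), which newly passed upward. It also turned for endoplasmic reticulum chaperones and immediate early genes (0.571 each), cell cycle (0.860) and endothelial markers (0.487), which did not pass. Since fry compares with no change and camera with the other genes, a list between the 2 can differ in direction. The median log2 fold change of all genes was 0.15. The lists that turned by fry had medians from 0.02 to 0.13, except leukocytes at 0.25. By ranks the call was lost for bile acid synthesis (0.0785), dilated cardiomyopathy (0.0781) and stretch (0.171), and peroxisome turned (0.892). The cause of the other changes was not tested.

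Under median-of-ratios scaling autophagy lost the call (0.259), and fatty acid oxidation (0.982) and heat shock (0.544) turned, and so did a further list: markers of macrophages and leukocytes (0.7998). Under quantile normalization stretch (0.145), matrix (0.133) and fibroblasts (0.693) lost the call, and fatty acid oxidation and peroxisome (0.916 each) and leukocytes (0.737) turned. With a mean of at least 5, autophagy lost the call (0.0551), and peroxisome and leukocytes (0.961 each) and heat shock (0.957) turned. The mitochondrial dynamics list turned with a pseudocount of 0.1 (0.995) and with no filter (0.887), and heat shock with a pseudocount of 5 (0.992). After thinning, bile acid synthesis lost the call (0.106), calcium handling passed (0.0251), and peroxisome (0.813), leukocytes (0.744) and the epicardial list (0.772) turned. The lists that turned did not pass before. The cause was not tested.

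Leaving out each library in turn, the adjusted p ran from 0.0148 to 0.127 for the inflammasome list, 0.0321 to 0.140 for bile acid synthesis and 0.0209 to 0.127 for autophagy. For lists that did not pass and turned in direction it ran from 0.596 to 0.897 for fatty acid oxidation, 0.665 to 0.862 for peroxisome, 0.942 to 0.982 for mitochondrial dynamics, 0.860 to 0.992 for heat shock and 0.825 to 0.984 for leukocytes. The other lists kept direction and call.

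Of the 149 named genes, 68 lost the call without control replicate 1, 33 without control replicate 2, 24 in the authors' deposited values, 21 in DESeq2, 14 with no filter, 11 under quantile normalization, 8 under median-of-ratios scaling and 8 with a pseudocount of 0.1, and 2 each without Crat hairpin replicate 1, with the robust prior, in edgeR and with mitochondrially encoded genes left out. Only genes that did not pass turned in direction. The log2 fold change of Fcer1g ran from -0.83 to 0.35 with a library left out, Laptm5 from -0.14 to 0.54 and Ncam1 from -0.16 to 0.28. The Laptm5 log2 fold change was -0.0024 under quantile normalization, -0.016 in edgeR and -0.027 in DESeq2. Ncam1 had -0.13 under median-of-ratios scaling, -0.083 under quantile normalization, -0.024 with mitochondrially encoded genes left out, -0.23 in edgeR and -0.17 in DESeq2. The cause was not tested.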

Other observations

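The tests below were chosen after the results were seen, except those of the actin and MHC class II lists, whose predictions were written before their values were looked at; all lists here were put together after the main results.

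Further lists, which share some members with the fixed ones, were looked at. Complement and acute phase genes rose in 14 of 15 cases and fell in 0, with C3 and Lcn2 also in the fixed cytokine list. Complement C2 rose from 15.6 and 8.32 to 1680 and 1608 RPM (reads scaled to the library total), the haem carrier Hpx by 5.82 on the log2 scale, the complement inhibitor Serping1 by 2.92, the siderophore binder Lcn2 by 2.74 and the phospholipase Pla2g2a by 2.29. Of 9 tested interferon-induced GTPases 8 rose, with Gbp4 at 6.31, Gbp2 at 6.16, Igtp at 4.95, Ifi47 at 4.93 and Irgm at 4.42. Gbp2, Gbp5, Mx1 and Mx2 among them were already counted in the fixed interferon list. Among 15 integrin genes 10 fell and 3 rose. Itgb1, the shared beta chain, fell from a mean of 4306 to 1702 RPM, and Itga11 fell by 1.95, while Itgb8 and Itga5 rose by 1.15 and 1.09. Of 7 S100 genes 4 fell, among them S100a4 by 1.34 and S100a6 by 1.23. S100b, also in a fixed list, did not pass.

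The fall of Acta1, Acta2, Cnn1 and Ccn2 led to the hypothesis that actin and serum response factor target genes fell as a group, and a list of 25 such genes outside the fixed lists was written before their values were seen. Of 24 tested, 18 fell and 2 rose, with a median log2 fold change of -0.58 against 0.15 for all genes (camera p = 3.7e-13; p = 0.0150 with an estimated correlation; permutation of 2 against 2 libraries cannot go below 0.333). Myh9 fell by 1.07, Actn1 by 0.90, Actb by 0.65 and Srf, the factor itself, by 0.69, while Tpm3 rose by 0.50; under median-of-ratios scaling 19 fell and 1 rose. Smooth muscle and pericyte markers fell too, in 10 of 14 cases, and fibroblast markers in 11 of 20. Lower activity of the factor and a smaller share of such cells are both open hypotheses, and neither was tested.

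A rise of MHC class II genes, as interferon gamma gives in many cells, was not seen and is not excluded. Of 9 listed genes 3 were in the table and 2 passed the filter, RT1-Bb at 0.24 ± 1.04 and RT1-DMb at 0.60 ± 0.73 (SE), neither past the threshold. The prediction had set fewer than 3 measured genes, or a median of 1 or less, as a negative result, and both held, with a median of 0.42. These bounds were set aside only after the result was seen: both errors reach past 1, and absence from the table can mean low expression, since no gene in it has fewer than 10 reads, or a gene left out for another reason.

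The rise of interferon-stimulated genes was the largest pattern. Cells of the immune system are argued against as its source: the highest knockdown group mean among the leukocyte markers was 11.1 RPM, for Cd68, while Irf7 reached 2114. The leukocyte list did pass upward in fry, which compares with no change and not with other genes (adjusted p = 0.0245), so a small share of such cells is not excluded. A single library is argued against too, since the lowest list median with a library left out was 4.28. Both groups were infected, so infection alone is shared. Whether the rise follows from loss of Crat, from other effects of its hairpin or from an unequal viral dose cannot be told apart, because the series has 0 groups beyond the 2 compared and the dose and the number of hairpins are not given in the sources used here. The fibroblasts in the culture, with Col1a1 at 7823 RPM in the controls, may also have responded.

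The fall of sarcomere genes is not explained by reads taken up by induced genes: under median-of-ratios scaling the list median was -1.05. A lower share of cardiomyocytes alone would raise the markers of all other cell types alike, but the medians of the fibroblast, smooth muscle, endothelial and leukocyte lists were -0.47, -1.21, 0.04 and 0.25, a range of 1.47 (permutation of genes among lists, p = 0.00762; genes are not independent replicates, and Des and Acta2 are also made by immature cardiomyocytes). Gene by gene the cardiomyocyte transcripts moved apart, with the calcium pump Atp2a2 up by 0.73 and Ryr2 at -0.02. A lower share of cardiomyocytes together with changes in the other cells would also spread these medians, so it is not excluded. A change within the cells after loss of Crat stays open as a hypothesis, and so does an effect of the hairpin on other targets or of an unequal viral dose.

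The mitochondrially encoded genes of the heavy strand fell more the farther they lie from its promoter. Over the 12 genes of that strand the rank correlation of order with log2 fold change was -0.85 (permutation p = 0.00103, two-sided, across genes, which are not independent). Expression level does not account for it: with the control level held fixed the partial rank correlation was -0.90 (permutation p = 2.1e-04). Nor does a single library, since the weakest of the 4 pairs of a Crat hairpin and a control library gave -0.85. The remaining gene, ND6, is not in that order and fell too, so position along the heavy strand does not cover its fall. Less complete transcription of the strand, or less stable distal transcripts, may underlie the grading; neither was tested, and nor was gene length.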
